A study of Rattus norvegicus with 46 samples.

How the data were processed

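The deposited files held 1 table of transcript counts for 46 libraries and 11 tables of gene results. Per the file headers and the submitters' processing notes, the transcript table holds estimated counts from kallisto 0.44.0, after bcl2fastq 2.19 had made the reads. The genome build and annotation are not given in the sources used here. In the authors' deposited gene tables, baseMean is the mean of gene counts divided by size factors, log2FoldChange and lfcSE are in log2 units, and pvalue and padj are p-values from DESeq2, whose version is not given in the sources used here. The sign of the deposited log2 fold change is the second-named group over the first, as found from the counts (correlation -0.999 with the opposite order).

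The transcript table carries no gene names, and no file used here pairs its transcripts with symbols. Names were therefore matched by value: a symbol was given to the 1, 2 or 3 transcripts whose counts, scaled like the authors' deposited tables, came close to the means in all 11 tables: within about 0.5 normalized counts for 1 transcript (9216 symbols) and up to about 1 for 2 or 3 (1198 and 58), else within 1% (1487 symbols of 1 and 855 of 2 transcripts) or 5% (217). This named 13031 of 23747 symbols and 15200 of 31715 transcripts, which hold 90.0% of all counts (88.1 to 95.3% per library). Of 12853 symbols with a mean of at least 50 in some table, 89.6% were matched. Searching for shifted values that no gene has gave 11 matches, so 0.0844% of names are expected to be wrong by chance. Over 124187 gene values the matched counts gave the deposited log2 fold change with a median absolute difference of 0.0045, and 99.1% were within 0.1. The tables share groups, so their matched means largely fix the fold changes too, and this closeness is no separate test of the names. Genes with near-identical copies, such as Hba-a1 and Hba-a2, share reads and were not told apart. Transcripts without a name stayed in the tests as features of their own.

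Counts were summed per symbol, rounded and filtered with filterByExpr, scaled with TMM and fitted with edgeR 4.0.16 quasi-likelihood (estimateDisp, glmQLFit robust, glmQLFTest) in R 4.3.3. One fit held the 17 bursa libraries (16373 features, 12665 with a symbol), another the 29 tendon libraries (16435 features, 12686 with a symbol), and another all 46 for contrasts between tissues (17304 features). Adjusted p is Benjamini-Hochberg over all features of a comparison. DESeq2 1.42.0 served as the alternative tool, and limma 3.58.1 gave camera.

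Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, at which no list passed in any of the 15 comparisons. There were 26 lists: skeletal muscle, adipocyte, tendon cell, fibrous matrix, matrix proteases, cartilage, bone forming cell, osteoclast, neutrophil, monocyte and macrophage, resident type macrophage, Spp1 and Trem2 type macrophage, T and NK cell, B cell, mast cell, inflammatory cytokines and chemokines, interferon response, cell division, endothelium, hypoxia and glycolysis, myofibroblast and TGF-beta, synovial lining, Schwann cell, mitochondrial respiration, immediate early, and red blood cell. A list needed 3 tested members, so the B cell list was not tested in tendon. Ranges after such counts are the lowest and highest as single libraries were left out, given where they span at least 5 genes. Where the text gives no count adjusted over the list alone, it was within 2 genes of the count over all features unless said otherwise.

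Groups, comparisons, tests, lists and most alternatives were chosen before the data were examined. Genes named are the 10 highest and 10 lowest without overlap between groups and with a mean of at least 10 CPM, members of the lists, and 10 genes fixed in advance (Scx, Mkx, Tnmd, Col1a1, Col3a1, Prg4, Il1b, Il6, Ccl2, Mki67). Each library was treated as 1 replicate. The series states that tendons were controlled within each rat, but the labels do not tie a library to a rat, so the p-values take libraries as independent. They would be too small or too large if 2 libraries come from the same animal. In removed against intact tendons most libraries of equal number correlated positively. A comparison within such pairs that ignores them tends to give p-values that are too large. A self-test used counts simulated from feature means and dispersions, with libraries independent and planted features at a mean of at least 1 CPM. A 2-fold change planted in 100 features was recovered for 56 to 82 and a 4-fold change for 80 to 99, depending on the comparison. The simulation held no pairs and no shared differences in muscle RNA, so recovery in the real libraries may differ. A first test for brown fat, which compared control bursae 1 and 2 with the other 3, was replaced by a correlation over all bursa libraries, because those 2 had been picked by a measured value. Those 2 libraries still weigh heavily in the correlation, which is thus not free of that choice. Results of 2 genes are not reported here.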

Results

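Gene expression was measured by sequencing of poly(A) RNA from the shoulder of rats. The supraspinatus tendon, part of the rotator cuff, had been cut (tenotomy), and the subacromial bursa, the thin sac of tissue that lies over this tendon, was left in place or taken out. Tendon and bursa were collected 3 or 14 days after the operation, and both tissues also came from rats that had not been operated on. The 46 libraries formed 8 groups. Control bursa and control tendon had 5 libraries each. The other 6 groups had 6 libraries each, namely injured bursa at day 3 and at day 14, and tendon at both days with the bursa intact or removed.

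Total estimated counts (M, mega) averaged 18.1 M ± 1.99 (SD, n = 5, range 15.5 to 20.4) in control bursa and 15.7 M ± 2.11 (n = 5, 12.4 to 18.3) in control tendon. Injured bursa had 17.1 M ± 2.07 (n = 6, 13.4 to 19.5) at day 3 and 28 M ± 20.9 (n = 6, 12.5 to 69.9) at day 14. Tendons with the bursa intact had 17.2 M ± 1.98 (n = 6, 13.5 to 18.9) at day 3 and 18.2 M ± 3.64 (n = 6, 14.2 to 22.5) at day 14. Tendons with the bursa removed had 15.5 M ± 1.02 (n = 6, 14.3 to 17.2) at day 3 and 19.7 M ± 2.62 (n = 6, 16.6 to 22.1) at day 14.

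Tissue content differed between groups before any gene was tested. Transcripts of the mitochondrial genome made up 29.2% ± 20.2 (SD, n = 5, range 13.3 to 53.5) of counts in control bursa and 30.9% ± 5.62 (n = 5) in control tendon. Their share was 12.1% ± 2.17 (n = 6) at day 3 and 8.89% ± 2.06 (n = 6) at day 14 in tendons with the bursa intact. Skeletal muscle transcripts, whose source was not tested, had a mean of 11.38 ± 0.34 log2 counts per M (CPM, SD, n = 5) in control tendon. That mean was 7.70 ± 0.56 in day 3 tendons with the bursa intact and 8.21 ± 1.18 in those with the bursa removed (n = 6 each).

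**Figure D1:**
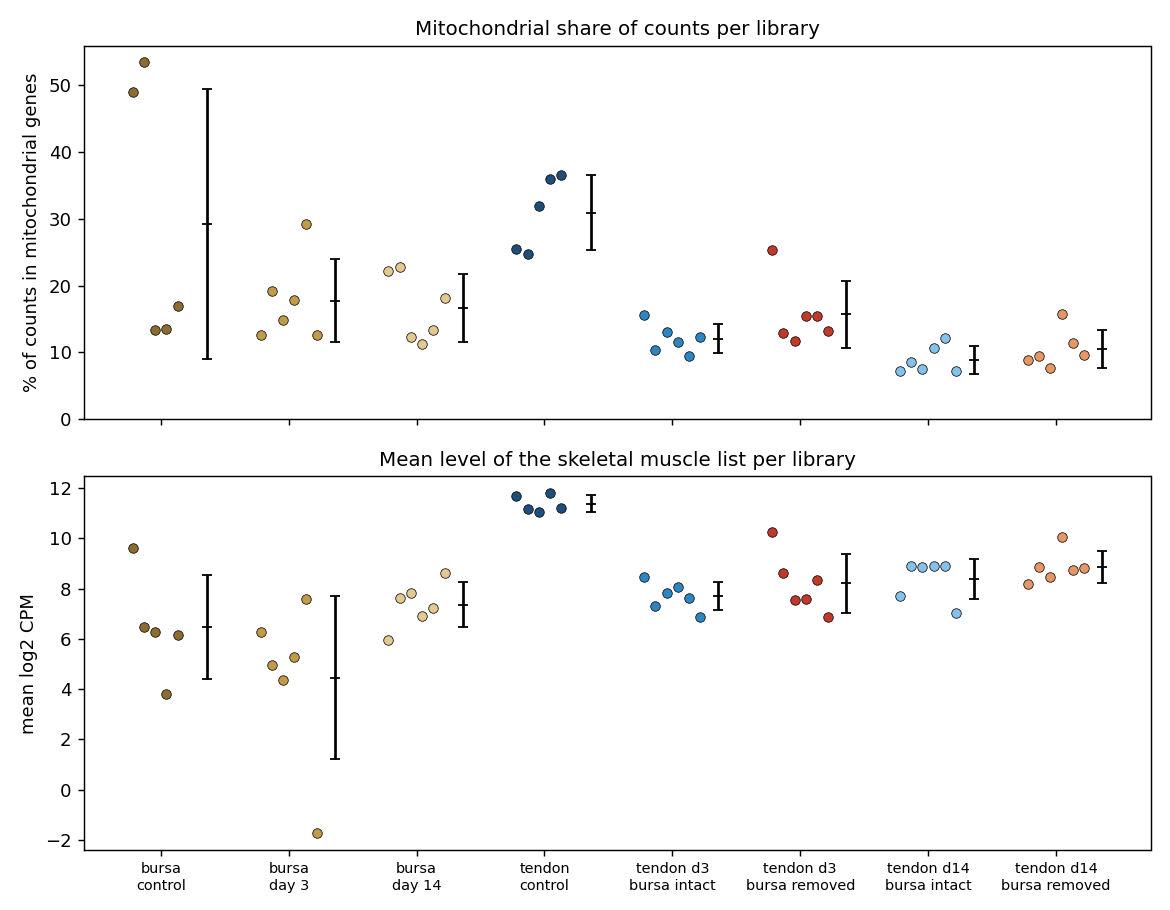
Share of mitochondrial transcripts and mean level of skeletal muscle transcripts for each of the 46 libraries, by group. Each point is 1 library.

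Throughout, gene values are log2 fold changes ± standard error from edgeR quasi-likelihood fits, p-values are Benjamini-Hochberg adjusted over all features tested (genes, and single transcripts that carry no symbol here), and levels are CPM ± SD. A gene rose or fell when its adjusted p was under 0.05. The lists of genes were fixed before the data were examined, and the examples named from each list were chosen after the values were seen.

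The first question was how the bursa itself responded 3 days after injury of the tendon beneath it (n = 6 injured, 5 control). Cell division and matrix genes rose strongly. Mki67, a marker of dividing cells, rose by 4.88 ± 0.35 (adjusted p = 8.2e-08), from 4.10 ± 1.95 to 124 ± 33.9 CPM, and all 16 cell division genes tested rose, among them Top2a (5.06 ± 0.38), which untangles DNA, and the cyclin Ccna2 (5.13 ± 0.34). The main fibre collagen gene Col1a1 rose by 3.73 ± 0.62 (adjusted p = 1.6e-04), from 1487 ± 1239 to 19732 ± 5442 CPM. Cthrc1 (5.55 ± 0.58) and Lrrc15 (6.51 ± 0.98), both made by activated fibroblasts, rose more. Of 17 fibrous matrix genes 13 rose and 0 fell, including Col3a1 (2.69 ± 0.51), the collagen of early scar, and Tnc (3.77 ± 0.91), a matrix protein of wounds. Adjusted over the list alone the counts were the same. Matrix proteases rose in 12 of 15 genes, for example Mmp14 (2.04 ± 0.38), and fell in 1.

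Immune cell genes rose with them. Of 13 monocyte and macrophage genes 11 rose, among them the lysosome gene Cd68 (2.33 ± 0.17) and the mannose receptor Mrc1 (2.03 ± 0.34). Of 7 genes of Spp1 and Trem2 type macrophages 6 rose, with Gpnmb at 4.06 ± 0.48 and Spp1 at 3.63 ± 1.18 (adjusted p = 0.02). The adjusted p of Spp1 was 0.058 when control bursae 1 and 2 were left out. The resident type macrophage list had 3 of 5 genes up, T and NK cells 6 of 9, with the T cell receptor partner Cd8a at 2.87 ± 0.31, neutrophils 3 of 5 and osteoclasts 3 of 4. Of 11 inflammatory cytokine and chemokine genes 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. Il1b rose by 1.85 ± 0.34 and the monocyte attractant Ccl7 by 2.96 ± 0.62. Il6 had 2.15 ± 0.646 CPM at day 3 and 0.0862 ± 0.118 CPM in control (adjusted p = 2.3e-04), while Ccl2 did not pass (1.31 ± 0.61, adjusted p = 0.088). Genes of the interferon response (0 of 13), B cells (0 of 3) and cartilage (0 of 3) did not pass.

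Fat, nerve and blood markers fell, and so did part of the tendon cell list. In the adipocyte list 8 of 9 genes fell and 0 rose, among them Plin1 (-1.69 ± 0.21), which coats the fat droplet, the hormone Lep (-2.87 ± 0.65) and Pck1 (-2.41 ± 0.47). Schwann cell genes fell in 6 of 8, with S100b at -2.27 ± 0.22, and red blood cell genes fell in 5 of 6, with the globin Hba-a1 at -2.01 ± 0.27. The lowest named genes were Myoc (-4.87 ± 0.60), Nnat (-4.57 ± 0.66) and the Wnt inhibitor Wif1 (-4.02 ± 0.89). Mitochondrial respiration genes fell in 12 of 13 (range 3 to 13), and in 0 without control bursae 1 and 2. The tendon cell list fell in 4 of 11, led by Chad (-6.11 ± 1.62), Cilp2 (-3.25 ± 1.14) and Fmod (-2.27 ± 0.78), and Chad was -0.76 (adjusted p = 0.54) without control bursa 4. That library had a mean tendon cell level of 6.11 log2 CPM, against 0.60 to 3.82 in the other control bursae. The source of these transcripts was not tested. Of the tendon regulators Scx (1.46 ± 0.74, adjusted p = 0.12), Mkx (-0.57 ± 0.65, adjusted p = 0.50) and Tnmd (-0.65 ± 0.71, adjusted p = 0.48) none passed, nor did the lubricant gene Prg4 (0.14 ± 0.71, adjusted p = 0.89).

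The remaining lists were mixed. Myofibroblast and TGF-beta genes rose in 6 and fell in 4 of 12. Immediate early genes, which respond to handling of tissue, rose in 2 and fell in 7 of 10 (range 3 to 8), with Fos at -1.62 ± 0.54. Endothelium had 1 up and 4 down of 10, hypoxia and glycolysis 1 up and 3 down of 10, synovial lining 1 up and 2 down of 7, and bone forming cells 1 up and 1 down of 3. Muscle fell in 2 of 11 and mast cells in 1 of 7, and both counts were 0 adjusted over the list alone. In all, 3611 features rose and 3965 fell of 16373 tested (3034 and 3261 of them with a symbol). With the replicate number as a block 3968 features were called, but injured and control bursae of equal number come from different rats, so this count does not measure pairing.

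The next comparison asked what was left of this response in the bursa at day 14 (n = 6 injured, 5 control). Matrix genes remained high. Col1a1 was 3.33 ± 0.60 above control (adjusted p = 0.0023) with 14932 ± 3571 CPM, Col3a1 was 2.62 ± 0.51 above, and Cthrc1 was 5.54 ± 0.58 above (adjusted p = 4.5e-05). Of 17 fibrous matrix genes 12 rose (range 9 to 16) and 0 fell, 13 adjusted over the list alone. Among the highest genes were Cpz (4.64 ± 0.44), a carboxypeptidase, the fibrillin Fbn2 (4.45 ± 0.82) and the matrix gene Spon1 (3.98 ± 0.32). Of 15 protease genes 9 rose, with Mmp2 at 1.58 ± 0.41 and Mmp14 at 2.00 ± 0.38. Mki67 was 2.10 ± 0.32 above control (adjusted p = 7.1e-04) at 18.0 ± 5.45 CPM, and all 16 cell division genes rose.

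T and NK cell and macrophage genes were also up. T and NK cell genes rose in 8 of 9, with the cytotoxic granule gene Nkg7 at 3.24 ± 0.48 and Cd3g at 2.15 ± 0.40. Macrophage genes rose in 9 of 13 (12 adjusted over the list alone), with Cd68 at 1.36 ± 0.16, and the macrophage lectin Siglec1 was among the highest genes (3.27 ± 0.51). Spp1 and Trem2 type genes rose in 3 of 7, resident type in 2 of 5, neutrophil in 2 of 5, osteoclast in 2 of 4 and bone forming cell genes in 2 of 3. Cytokine genes rose in 5 and fell in 1 of 11, with Il1b at 1.58 ± 0.33 (adjusted p = 0.0051). Interferon response genes rose in 3 of 13, namely Mx1 (4.65 ± 1.33), Irf7 (3.05 ± 0.89) and Cxcl10 (4.48 ± 1.41), and in 10 adjusted over the list alone (range 0 to 5 over all features). This rise depended on replicate 6, without which Mx1 was 1.26 (adjusted p = 0.15).

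Falls were fewer than at day 3. The adipocyte list fell in 1 of 9, Plin1 (-0.76 ± 0.21), endothelium in 3 of 10, immediate early genes in 3 of 10 and Schwann cells in 1 of 8. Myofibroblast and TGF-beta genes rose in 4 of 12, and synovial lining (1 up, 2 down of 7) and hypoxia genes (1 up, 1 down of 10) were mixed. The lowest named genes were Pla2g2a (-2.30 ± 0.47), a phospholipase, and the cytokine-like gene Cytl1 (-2.22 ± 0.48). The tendon cell list had 1 up and 2 down of 11, with Chad at -4.73 ± 1.47, which was 0.61 (adjusted p = 0.68) without control bursa 4. Tnmd (1.73 ± 0.73, adjusted p = 0.11) and Prg4 (-1.42 ± 0.72, adjusted p = 0.18) did not pass. No gene of the red blood cell, muscle, mast cell, B cell, cartilage or respiration lists passed, with Hba-a1 at -0.75 ± 0.26 (adjusted p = 0.062) and Ndufs1 of complex I at -0.91 ± 0.53 (adjusted p = 0.24). In all, 1519 features rose and 1173 fell. With the replicate number as a block 251 features were called, but injured and control bursae of equal number come from different rats, so this count does not measure pairing.

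Day 14 was then set against day 3 in the injured bursa, to ask which genes moved during healing (n = 6 each). Cell division fell away. Mki67 fell by 2.78 ± 0.29 (adjusted p = 1.2e-05), Top2a by 2.95 ± 0.31, and all 16 genes of the list fell (camera adjusted p = 3.6e-21, adjusted p = 0.29 with an estimated correlation). Col1a1 (-0.40 ± 0.51, adjusted p = 0.62) and Col3a1 (-0.07 ± 0.45, adjusted p = 0.93) did not pass, nor did any of the 17 fibrous matrix genes. Il6 fell by 2.95 ± 0.60 (adjusted p = 0.0025) and cytokine genes fell in 3 of 11. Macrophage genes fell in 4 of 13 and Spp1 and Trem2 type genes in 3 of 7, with Gpnmb at -1.96 ± 0.41.

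Part of the fat, nerve and blood markers rose. Adipocyte genes rose in 4 of 9 with Plin4 at 1.59 ± 0.28, Schwann cell genes in 5 of 8 with S100b at 1.14 ± 0.21, and red blood cell genes in 4 of 6 with Hba-a1 at 1.26 ± 0.26. The tendon cell list rose in 2 of 11, Cilp2 (3.33 ± 1.12) and Tnmd (2.37 ± 0.70, adjusted p = 0.024). T and NK cell genes rose in 4 (range 1 to 6) and fell in 2 of 9, with Cd3g at 1.15 ± 0.36, and interferon genes rose in 4 of 13 (range 1 to 6), with Mx1 at 3.91 ± 1.18 and Irf7 at 3.23 ± 0.83. The transcription factor Zbtb16 (3.74 ± 0.50), Myoc (2.53 ± 0.54) and the actin-severing gene Gsn (2.15 ± 0.34) were among the highest. Without day 14 replicate 6 Mx1 was 0.51 (adjusted p = 0.55) and Irf7 1.13 (adjusted p = 0.022), and without day 3 replicate 3, 4 or 6 Mx1 missed the threshold (adjusted p = 0.057, 0.053 and 0.054). Proteases had 1 up and 5 down of 15, neutrophils 1 up and 3 down of 5, and myofibroblast genes 3 down of 12. In all, 1552 features rose and 2007 fell.

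For the tendon, the first question was how it answered tenotomy within 3 days while the bursa was in place (n = 6 injured, 5 control). Inflammatory, dividing and matrix-degrading programmes rose together. The collagenase gene Mmp13 went from 0.0249 ± 0.0557 to 127 ± 101 CPM and Il6 from 0.0508 ± 0.0782 to 4.99 ± 2.71 CPM. Mki67 rose by 4.83 ± 0.18 (adjusted p = 3.5e-17), and all 16 cell division genes rose, with Top2a at 5.53 ± 0.30. Of 16 proteases 15 rose, including the stromelysin Mmp3 (4.02 ± 0.60). Of 12 cytokine and chemokine genes 11 rose, including Il1b (4.32 ± 0.46), Ccl2 (2.66 ± 0.44), Ccl7 (4.16 ± 0.39) and the prostaglandin enzyme Ptgs2 (5.14 ± 0.67). The haem-degrading enzyme gene Hmox1 was among the highest genes (6.37 ± 0.32).

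Blood cell markers followed the same direction. All 13 macrophage genes rose, with Cd68 at 2.88 ± 0.18, as did all 8 T and NK cell genes, with Cd8a at 4.36 ± 0.47. Spp1 and Trem2 type genes rose in 5 and fell in 1 of 7, with Gpnmb at 3.83 ± 0.20 and the arginase Arg1 at 4.76 ± 0.69. Neutrophil genes rose in 4 of 5, with the growth factor receptor Csf3r at 5.04 ± 0.29, mast cell genes in 4 of 7 and osteoclast genes in 4 of 5. Resident type macrophage genes had 3 up and 2 down of 5. Red blood cell genes rose in 4 and fell in 1 of 5, with Hba-a1 at 1.77 ± 0.29. Interferon genes had 3 up and 1 down of 13, and 1 up and 1 down adjusted over the list alone.

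Matrix genes rose while markers of mature tendon fell. Col1a1 rose by 2.32 ± 0.27 (adjusted p = 2.7e-08), from 4775 ± 2837 to 23819 ± 4459 CPM, Col3a1 by 2.88 ± 0.18, the scar matrix gene Postn by 4.94 ± 0.29 and Lrrc15 by 5.10 ± 0.28. Of 17 fibrous matrix genes 14 rose and 1 fell. Of 11 tendon cell genes 9 fell and 0 rose (camera adjusted p = 1.0e-04, adjusted p = 0.28 with an estimated correlation). Chad, which binds cells to collagen, fell by 8.07 ± 0.65 (adjusted p = 3.8e-11), from 1209 ± 548 to 4.48 ± 3.16 CPM. Kera (-3.22 ± 0.36) and Fmod (-2.50 ± 0.23), which space collagen fibrils, Mkx (-2.24 ± 0.28) and Tnmd (-1.27 ± 0.27, adjusted p = 2.0e-04) also fell. Scx (-0.18 ± 0.24, adjusted p = 0.51) and Prg4 (0.53 ± 0.28, adjusted p = 0.10) did not pass. Cartilage genes had 1 up and 5 down of 7, with Col2a1 at -5.42 ± 1.28.

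Muscle and energy genes were lower in the same tendons. All 11 muscle genes fell, among them Ckm (-3.29 ± 0.52), Myl2 (-5.28 ± 0.68) and Acta1 (-3.42 ± 0.52), and so did all 13 respiration genes, with Ndufs1 at -1.84 ± 0.19. With the muscle level as a covariate Ckm was 0.45 and the features called numbered 3486 in place of 10792, of which 5106 had risen and 5686 had fallen. Adipocyte genes fell in 7 of 9 and Schwann cell genes in 6 of 8, with S100b at -3.24 ± 0.21 and 1 up. Myofibroblast genes had 7 up and 3 down of 12, bone forming cell genes 2 up and 3 down of 6, endothelium 1 up and 4 down of 10 and hypoxia genes 3 up and 4 down of 10. Immediate early genes had 1 up and 4 down of 10 and synovial lining 2 up and 2 down of 7.

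**Figure D2:**
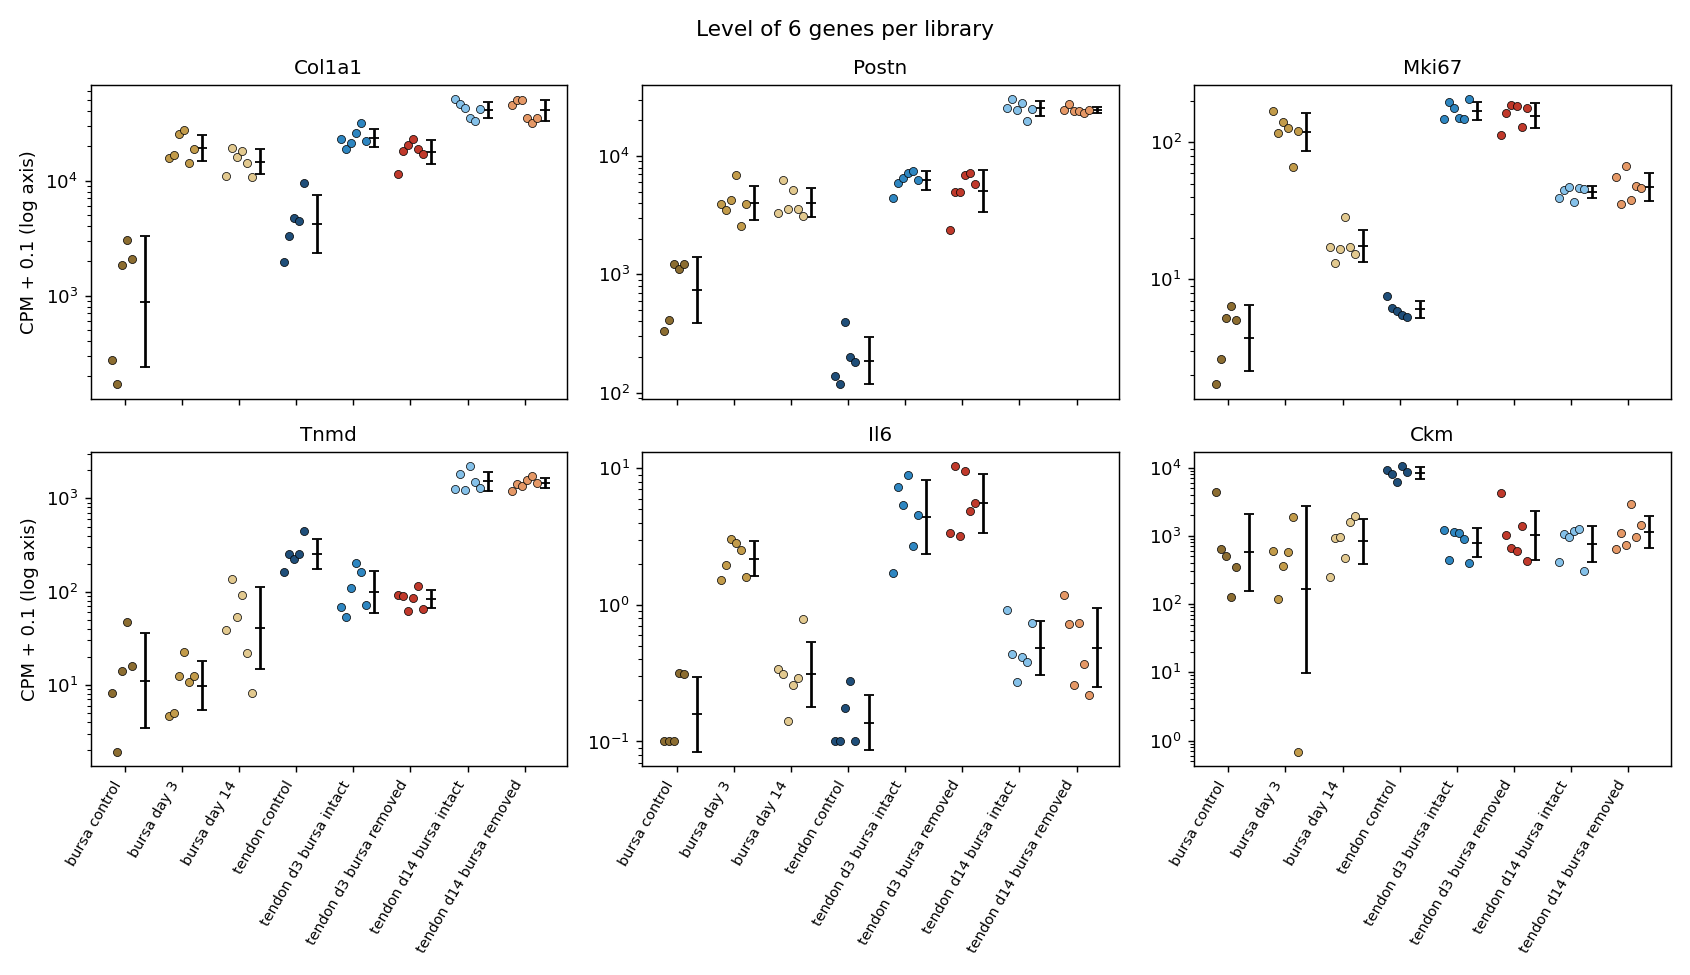
Levels of 6 genes (Col1a1, Postn, Mki67, Tnmd, Il6 and Ckm) in every library by group, in CPM + 0.1 on a log axis. Bars are the mean ± SD of the log10 values.

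The same question was put to day 3 tendons whose bursa had been removed (n = 6 injured, 5 control). Mmp13 reached 187 ± 100.1 CPM and Il6 6.05 ± 3.11 CPM. Mki67 rose by 4.72 ± 0.18, Postn by 4.71 ± 0.29, Col1a1 by 1.93 ± 0.27 (adjusted p = 5.2e-07), Ccl2 by 2.67 ± 0.44, Ptgs2 by 4.20 ± 0.67 and Cd68 by 2.85 ± 0.18. Chad fell by 7.56 ± 0.63, Kera by 3.30 ± 0.36, Tnmd by 1.66 ± 0.28 and Mkx by 1.97 ± 0.28. Cell division rose in 16 of 16 genes, proteases in 15 of 16, cytokines in 11 of 12, macrophages in 11 of 13, T and NK cells in 8 of 8 and neutrophils in 4 of 5. Fibrous matrix had 14 up and 2 down of 17, and the tendon cell list 9 down of 11.

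Other lists in these tendons also moved. Muscle fell in 11 of 11, with Ckm at -2.59 ± 0.51, and respiration in 13 of 13, while the muscle covariate gave 4485 features called in place of 10358 and brought Ckm to 0.26. Schwann cell genes had 1 up and 7 down of 8, cartilage 1 up and 5 down of 7, adipocytes 4 down of 9 (range 2 to 8), myofibroblast genes 7 up and 3 down of 12 and Spp1 and Trem2 type genes 5 up and 1 down of 7. Mast cell genes rose in 4 of 7, osteoclast genes in 4 of 5, red blood cell genes in 4 of 5 and interferon genes in 3 of 13. Resident type macrophages had 3 up and 2 down of 5, endothelium 2 up and 2 down of 10, hypoxia 2 up and 4 down of 10, bone forming cells 2 up and 2 down of 6, synovial lining 2 up and 2 down of 7 and immediate early genes 1 up and 5 down of 10. In all, 4874 features rose and 5484 fell.

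At day 14 with the bursa intact, the question was which part of the tendon response had matured (n = 6 injured, 5 control). Matrix genes rose strongly. Cthrc1 rose by 7.54 ± 0.25 (adjusted p = 2.8e-18), from 5.72 ± 2.45 to 1054 ± 84.5 CPM, and Postn by 6.96 ± 0.32, from 205 ± 110.0 to 25548 ± 3522 CPM. Lrrc15 (6.75 ± 0.29), Col1a1 (3.13 ± 0.28), Col3a1 (3.27 ± 0.19) and Col12a1 (4.68 ± 0.25), which decorates collagen fibres, also rose. Of 17 fibrous matrix genes 16 rose and 1 fell (camera adjusted p = 1.2e-09, adjusted p = 0.45 with an estimated correlation). Proteases rose in 14 of 16, with Mmp14 at 5.02 ± 0.20, and Mmp13 stood at 25.2 ± 7.32 CPM. The protease gene Prss35 was among the highest (7.44 ± 0.36).

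Tendon and cartilage genes split. Tnmd, a marker of maturing tendon cells, rose by 2.54 ± 0.29 (adjusted p = 2.7e-08), from 268 ± 106 to 1559.6 ± 389 CPM, and Scx by 1.29 ± 0.24, while Chad fell by 6.91 ± 0.61, Angptl7 fell by 4.20 ± 0.52 and Mkx by 0.60 ± 0.26 (adjusted p = 0.049), a call lost in 9 of 11 fits that left out 1 library and in most other alternatives, with 0.11 under the muscle covariate. In the tendon cell list 3 genes rose and 5 fell of 11. The cartilage list had 2 up and 4 down of 7, and the 2 were Matn3 (5.75 ± 0.35) and Col11a1 (3.50 ± 0.31). Bone forming cell genes had 3 up and 2 down of 6. Prg4 fell by 1.68 ± 0.28 (adjusted p = 8.5e-06), and synovial lining genes had 2 up and 3 down of 7. Among the lowest genes were Pla2g2a (-6.36 ± 0.39), Coch (-6.27 ± 0.68) and Wif1 (-5.30 ± 0.61).

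Immune and dividing cell genes were still up. Mki67 rose by 2.85 ± 0.17 with all 16 cell division genes, Cd68 by 1.398 ± 0.171 with 9 of 13 macrophage genes, and T and NK cell genes in 8 of 8. Il1b (3.60 ± 0.47) and Ptgs2 (4.50 ± 0.67) were among 6 of 12 cytokine genes that rose, and Ccl2 did not pass (0.26 ± 0.42, adjusted p = 0.60). Spp1 and Trem2 type genes had 4 up and 1 down of 7, resident type 1 up and 2 down of 5, neutrophils 3 up of 5, osteoclasts 3 up of 5, red blood cells 4 up of 5 and myofibroblast genes 8 up of 12. Mast cells had 1 up of 7, and 0 adjusted over the list alone.

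All 11 muscle genes fell, with Ckm at -3.29 ± 0.52, all 13 respiration genes fell, with Ndufs1 at -1.78 ± 0.19, and 8 of 9 adipocyte genes fell, with Lep at -5.02 ± 1.05. Schwann cell genes fell in 5 of 8, endothelium in 6 of 10 (range 2 to 9), interferon genes in 3 of 13, immediate early genes had 1 up and 2 down of 10, and hypoxia genes 1 up and 5 down of 10. In all, 5450 features rose and 5444 fell, and 4976 were called with the muscle covariate.

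The day 14 tendons with the bursa removed were put to the same question (n = 6 injured, 5 control). Cthrc1 rose by 7.42 ± 0.25, Postn by 6.91 ± 0.32, Col1a1 by 3.12 ± 0.28 (adjusted p = 3.9e-10), Tnmd by 2.45 ± 0.29, Scx by 1.31 ± 0.24, Mmp14 by 4.89 ± 0.20 and Mki67 by 3.01 ± 0.17. Mmp13 stood at 30.2 ± 7.20 CPM. Chad fell by 6.74 ± 0.61, Prg4 by 1.67 ± 0.28 and Ckm by 2.69 ± 0.51. Fibrous matrix had 16 up and 1 down of 17, proteases 14 up of 16, cell division 16 up of 16, macrophages 9 up of 13, T and NK cells 8 up of 8 and cytokines 9 up of 12, a count that ranged from 5 to 9 as single libraries were left out. The tendon cell list had 3 up and 5 down of 11.

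Muscle fell in 11 of 11 genes, respiration in 13 of 13, adipocytes in 8 of 9 and Schwann cells in 5 of 8. Cartilage had 2 up and 4 down of 7, bone forming cells 3 up and 2 down of 6, osteoclasts 4 up of 5, neutrophils 3 up of 5, red blood cells 4 up of 5 and myofibroblast genes 8 up of 12. Spp1 and Trem2 type genes had 4 up and 1 down of 7, resident type 2 up and 2 down of 5, mast cells 1 up of 7, interferon 3 down of 13, endothelium 2 down of 10, hypoxia 1 up and 5 down of 10, synovial lining 2 up and 4 down of 7 and immediate early genes 1 up and 3 down of 10. In all, 5355 features rose and 5363 fell, and 5855 were called with the muscle covariate.

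**Figure D3:**
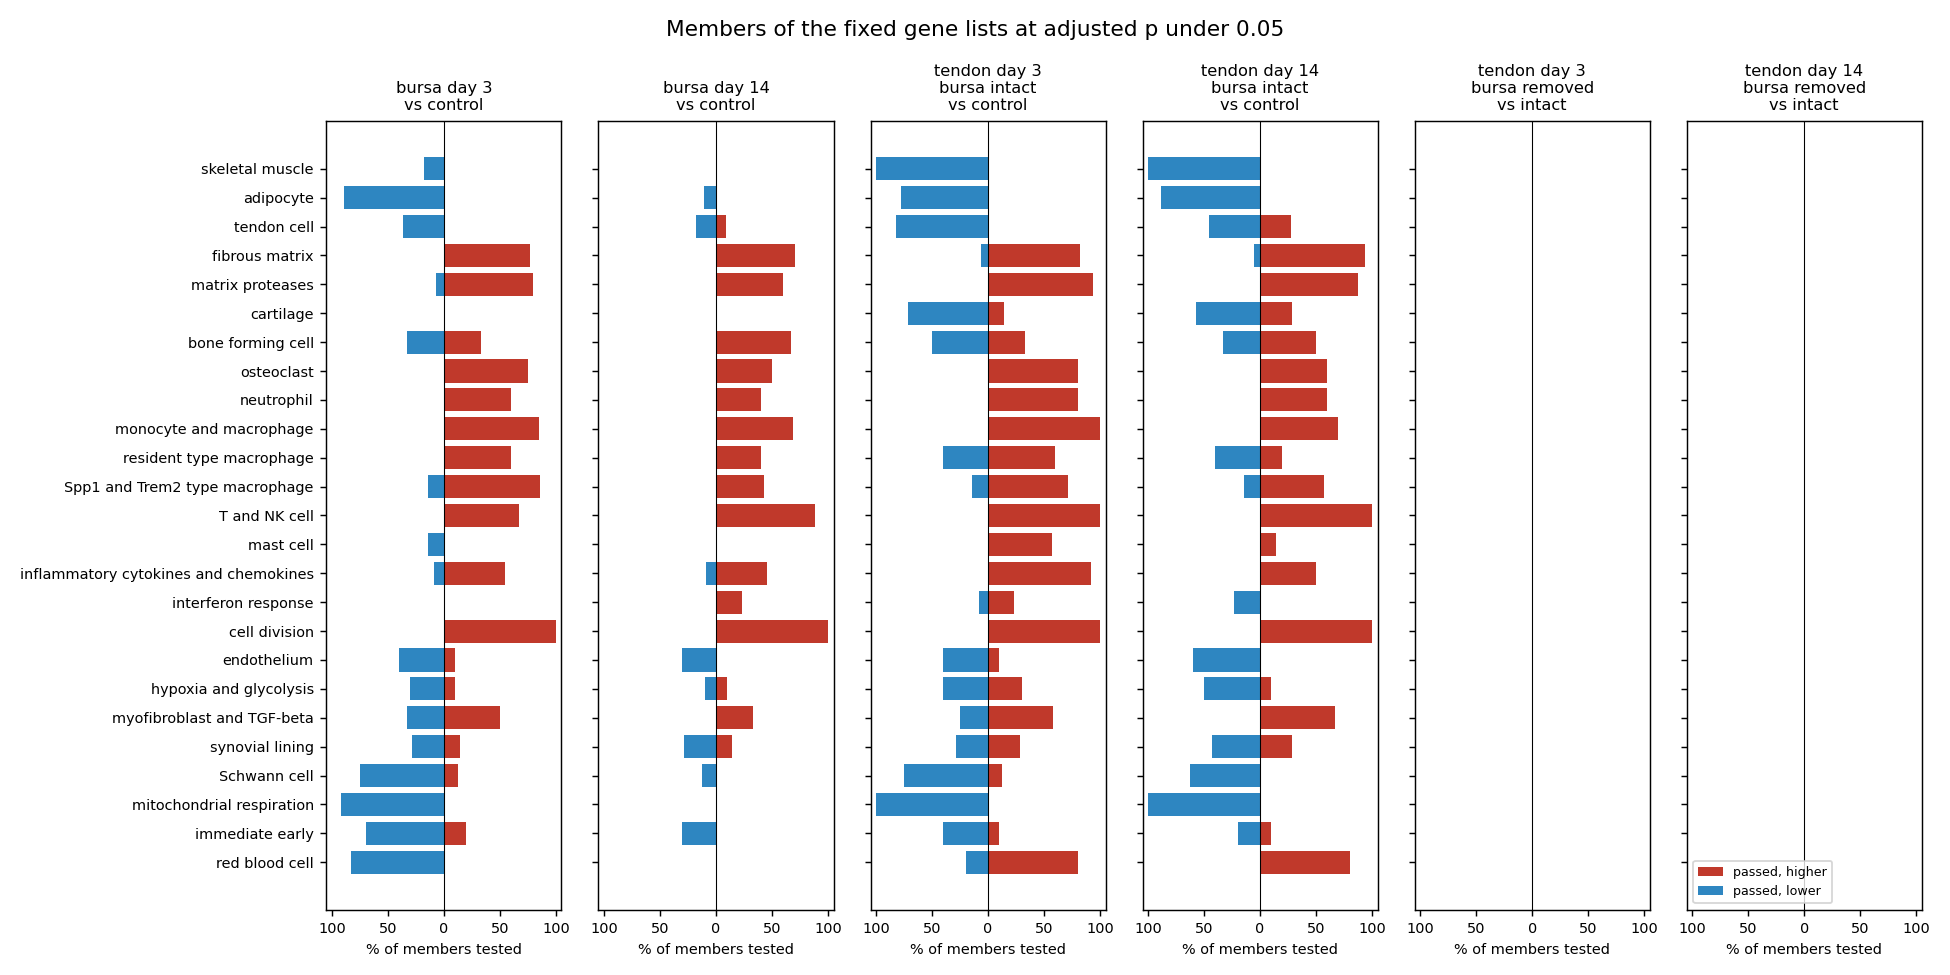
Percent of the tested members of each gene list that rose or fell (adjusted p under 0.05) in 6 comparisons.

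The central question of the design was whether removing the bursa changes the injured tendon. At day 3 (n = 6 each) the edgeR quasi-likelihood fit called 0 of 16435 features, with the smallest adjusted p at 0.225. Unadjusted p was under 0.05 for 1289 features (7.84%), and DESeq2 called 12. An edgeR fit with the replicate number as a block also called 0 features, with 1610 unadjusted p-values under 0.05. Col1a1 (-0.39 ± 0.24, adjusted p = 0.64), Mki67 (-0.11 ± 0.14, adjusted p = 0.83), Il6 (0.28 ± 0.43, adjusted p = 0.87), Scx (-0.09 ± 0.22) and Tnmd (-0.38 ± 0.26) did not pass. Of the 12 features, 5 had a gene symbol, looked up after the values were seen: with DESeq2 the membrane gene Tspan15 was 0.82 higher without the bursa, and the matrix gene Dpt (-0.64), the sugar transferase Galnt16 (-0.76), the transcription factor Osr2 (-0.84) and Rab15 (-0.57) were lower. The transcripts without a symbol ranged in DESeq2 log2 fold change from -25.3 to 20.6, and values as large as these ends cannot be read as measured effects. The median standard error in edgeR was 0.147. In a self-test on counts simulated for independent libraries, a 2-fold change planted in 100 features was recovered for 82 and a 4-fold change for 94. The simulation held none of the pairing or shared muscle differences of these tendons, so it does not give the power of this comparison. The 2 groups did not overlap for 45 features (0.274%, against 0.216% by chance).

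Some genes leaned to 1 side at day 3 without passing over all features. Ptgs2 (-0.93 ± 0.46, adjusted p = 0.62), the growth factor gene Inhba (-0.58 ± 0.31) and the crosslinking enzyme Loxl2 (-0.52 ± 0.17) leaned lower without the bursa, and the endothelial junction genes Cldn5 (0.63 ± 0.19) and Cdh5 (0.44 ± 0.17) leaned higher. Adjusted over the list alone, 4 list genes passed, seen after the values were known: Ibsp (3.22 ± 1.04), Cldn5 and Tspan15 (0.82 ± 0.19) higher and Lrrc15 (-0.71 ± 0.20) lower. With camera, 10 lists were called, and the lowest adjusted p was 0.59 with an estimated correlation. They were lower for fibrous matrix (8.4e-06), hypoxia, immediate early, cell division and myofibroblast genes and higher for endothelium (1.1e-04), respiration (2.5e-04), muscle, interferon and adipocyte genes. Ckm, the muscle marker, was 0.70 ± 0.47 (adjusted p = 0.66), and the muscle covariate gave 714 unadjusted p-values under 0.05. Removed replicate 1 had a mean muscle level of 10.27 log2 CPM, against 6.88 to 8.62 in the others of its group. Without it, Ckm against control was -3.35 in removed tendons, next to -3.29 in intact tendons. Camera was not repeated without this library.

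At day 14 (n = 6 each) edgeR called 0 features and the smallest adjusted p was 1.00. Unadjusted p was under 0.05 for 214 features (1.302%), and DESeq2 called 2 features, both transcripts left without a gene symbol here. Their DESeq2 log2 fold changes of -25.6 and 21.7 are too large to be read as measured effects. With the replicate number as a block, which took equal numbers as pairs, edgeR called 0 features and 646 unadjusted p-values were under 0.05. Postn (-0.05 ± 0.23), Cthrc1 (-0.12 ± 0.17), Col1a1 (-0.01 ± 0.24), Mmp13 (0.26 ± 0.40), Ptgs2 (-0.20 ± 0.46) and Mki67 (0.16 ± 0.14) did not pass (adjusted p = 1.00 each). The standard errors of Mmp13 and Ptgs2 leave room for a difference in either direction. In the self-test on simulated counts 82 of 100 features with a 2-fold change were recovered, which does not give the power with paired libraries. The camera lists called were higher without the bursa, namely muscle (0.0021), respiration (0.0021), cell division (0.0040) and endothelium (0.028), with adjusted p = 0.96 with an estimated correlation for the lowest. Ckm was 0.60 ± 0.47.

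Whether the effect of bursa removal itself changed between the days was tested as an interaction (n = 6 in each of 4 groups). edgeR called 0 features, unadjusted p was under 0.05 for 254, and DESeq2 called 1, a transcript left without a gene symbol here. Its DESeq2 log2 fold change of 23.3 is too large to be read as a measured effect. The difference was 0.74 ± 0.65 for Ptgs2, 0.38 ± 0.34 for Col1a1 and 0.27 ± 0.20 for Mki67 (adjusted p = 1.00 each). With camera 8 lists were called, 4 up, namely cell division (6.5e-05), fibrous matrix (5.7e-04), hypoxia and myofibroblast genes, and 4 down, namely interferon (0.0038), neutrophil, endothelium and T and NK cell genes, and the lowest adjusted p was 0.61 with an estimated correlation.

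In the authors' deposited table for removed against intact at day 3, 82 genes had an adjusted p under 0.05, 51 higher with the bursa intact and 31 higher with it removed. An adjusted p was given there for 7928 of 23747 symbols, fewer than the features tested here, but this need not be why more genes were called. Ptgs2 had an adjusted p of 3.7e-05 there with DESeq2. It did not pass in the edgeR fit here, which took libraries as independent. The deposited standard errors were not compared with those here, and why the calls differ was not tested. In the authors' deposited table Ptgs2 was 1.05 higher with the bursa intact, as were the matrix genes Dpt (0.71), Aspn (0.46), Lox (0.46) and Plod2 (0.39). The embryonic muscle genes Myl4 (1.06), Myog (0.94) and Chrnd (0.86) were higher with the bursa removed in the authors' deposited table. In the authors' deposited table for day 14 the number of such genes was 2, Mustn1 (0.52) and LOC100912571 (0.73), both higher with the bursa removed. At day 14 18480 symbols had an adjusted p, so the counts of the 2 days are not over the same genes.

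The change of the injured tendon between day 3 and day 14 was asked first with the bursa intact (n = 6 each). Tendon cell genes rose. Tnmd rose by 3.81 ± 0.29 (adjusted p = 8.6e-11), Scx by 1.48 ± 0.23, Mkx by 1.64 ± 0.27, Cilp2 by 4.18 ± 0.34, Kera by 2.94 ± 0.34 and Fmod by 2.32 ± 0.23, and 9 of 11 tendon cell genes rose (camera adjusted p = 1.6e-06, adjusted p = 0.36 with an estimated correlation). Postn (2.02 ± 0.24), Col12a1 (1.56 ± 0.21) and Col1a1 (0.81 ± 0.24, adjusted p = 0.0083) were among 13 of 17 fibrous matrix genes that rose, and Col3a1 did not pass (0.39 ± 0.16, adjusted p = 0.051). Matn3 rose by 4.41 ± 0.27 with 3 of 7 cartilage genes. The highest gene was Pamr1 (6.13 ± 0.36), a serine protease-like gene of muscle repair, with the sulfotransferase gene Chst5 at 5.41 ± 0.27.

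Inflammation and division fell over the same time. Mki67 fell by 1.99 ± 0.14 and Top2a by 2.05 ± 0.22, with 16 of 16 cell division genes. Il6 fell by 3.50 ± 0.51, Ccl2 by 2.40 ± 0.40 and 7 of 12 cytokine genes fell, while Il1b did not pass (-0.72 ± 0.32, adjusted p = 0.066). Macrophage genes fell in 11 of 13, Spp1 and Trem2 type genes in 6 of 7 with 1 up, among them Gpnmb (-1.85 ± 0.17) and Arg1 (-2.83 ± 0.53), resident type in 3 of 5, neutrophil in 3 of 5 with Csf3r at -2.64 ± 0.21, T and NK cell in 3 of 8 and mast cell in 3 of 7. Proteases exchanged places: Mmp3 (-2.28 ± 0.51) and Mmp13 (-2.33 ± 0.41) were among 6 of 16 that fell, and Mmp14 (1.70 ± 0.16) among 4 that rose. Prg4 fell by 2.21 ± 0.28 and Hmox1 by 2.90 ± 0.25.

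Hypoxia genes fell in 6 of 10, interferon genes in 2 of 13 and adipocyte genes in 2 of 9, and muscle rose in 2 of 11. Myofibroblast genes had 4 up and 1 down of 12, bone forming cells 3 up and 2 down of 6, Schwann cells 3 up and 1 down of 8, synovial lining 3 up and 2 down of 7, immediate early genes 3 up and 2 down of 10, and endothelium and osteoclasts 1 up and 1 down each. Respiration and red blood cell genes did not pass. In all, 3683 features rose and 3372 fell.

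With the bursa removed the same change was measured (n = 6 each). Tnmd rose by 4.10 ± 0.29 (adjusted p = 3.4e-11), Cilp2 by 4.09 ± 0.34, Scx by 1.59 ± 0.23, Postn by 2.20 ± 0.24 and Col1a1 by 1.18 ± 0.24, and Mki67 fell by 1.72 ± 0.14, Il6 by 3.65 ± 0.51, Ccl2 by 2.42 ± 0.40, Mmp13 by 2.64 ± 0.41 and Prg4 by 2.08 ± 0.28. The acetylcholine receptor genes Chrna1 (-3.97 ± 0.37) and Chrnd (-3.28 ± 0.34) and the muscle regulator Myog (-3.07 ± 0.43) were among the lowest. Tendon cell genes rose in 9 of 11, fibrous matrix in 15 of 17 and cartilage in 4 of 7. Cell division fell in 16 of 16 genes, macrophages in 9 of 13, cytokines in 8 of 12, neutrophils in 4 of 5, Spp1 and Trem2 type in 6 of 7 with 1 up, and T and NK cells in 4 of 8.

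Proteases had 4 up and 6 down of 16, myofibroblast genes 7 up and 1 down of 12, resident type macrophages 1 up and 3 down of 5, and interferon 6 down of 13. Adipocytes fell in 5 of 9, a count that ranged from 1 to 7 as single libraries were left out, and respiration in 3 of 13 (range 0 to 7, and 0 adjusted over the list alone). Muscle had 1 up and 1 down of 11, bone forming cells 3 up and 2 down of 6, osteoclasts 2 up and 1 down of 5, mast cells 2 down of 7, endothelium 2 down of 10, hypoxia 3 down of 10, synovial lining 3 up and 2 down of 7, Schwann cells 2 up and 1 down of 8 and immediate early genes 3 up and 1 down of 10. Red blood cell genes did not pass. In all, 3845 features rose and 3585 fell.

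The tissues were compared without injury to ask what sets the bursa apart from the tendon (n = 5 each). The bursa had more fat, mast cell and blood cell transcripts. Plin1 was 6.34 ± 0.87 higher in bursa, Pck1 7.57 ± 1.08 and Lep 6.04 ± 0.81, and 9 of 9 adipocyte genes were higher (camera adjusted p = 9.3e-10, adjusted p = 0.12 with an estimated correlation). All 7 mast cell genes were higher, with the carboxypeptidase Cpa3 at 4.21 ± 0.62, 8 of 9 T and NK cell genes, with Cd8a at 2.45 ± 0.47, 4 of 6 red blood cell genes, with Hba-a1 at 5.68 ± 0.35, and 4 of 5 neutrophil genes. Macrophage genes had 7 higher and 2 lower of 13, cytokines 5 higher of 14 (range 2 to 7), with Il1b at 2.89 ± 0.48, and interferon genes 4 higher of 13.

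Tendon genes were lower in bursa in 10 of 11 and higher in 1. Scx was -3.53 ± 0.54, Mkx -4.08 ± 0.46, Tnmd -3.92 ± 0.58, Fmod -2.58 ± 0.57 and Col1a1 -1.67 ± 0.42, and the lowest gene was Coch (-9.50 ± 0.92). Prg4 was lower too, with 195 ± 274 CPM in bursa and 1836 ± 459.5 CPM in tendon. Muscle was lower in 10 of 11 genes, with Myl2 at -5.68 ± 0.97 and Ckm at -2.82 ± 0.88, which was 1.398 with the muscle covariate. Control bursa 1 stood apart, with a mean muscle level of 9.60 log2 CPM against 3.82 to 6.47 in the other control bursae. Col3a1 (0.12 ± 0.34, adjusted p = 0.80) and Mki67 (-0.50 ± 0.25, adjusted p = 0.088) did not pass. Fibrous matrix had 1 higher and 7 lower of 17, myofibroblast genes 4 higher and 7 lower of 12, synovial lining 1 higher and 5 lower of 7, cartilage 1 higher and 4 lower (range 2 to 7) of 8 and Spp1 and Trem2 type genes 1 higher and 4 lower of 7, with Spp1 at -5.73 ± 0.92.

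Proteases had 7 higher and 3 lower of 16, endothelium 6 higher of 10, Schwann cells 3 higher of 8, respiration 3 higher of 13 (range 1 to 7), osteoclasts 2 higher of 5, B cells 2 higher of 3, resident type macrophages 2 higher and 1 lower of 5, hypoxia 2 higher and 4 lower of 10, immediate early genes 1 higher and 2 lower of 10, bone forming cells 1 higher and 1 lower of 6 and cell division 1 lower of 16. In all, 5054 features were higher and 3807 lower in bursa, of 17304 tested, and 4811 were called with the replicate number as a block.

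Last, the change at day 3 in bursa was tested against that in tendon with the bursa intact, as an interaction (n = 6, 5, 6 and 5). A gene is called lower when its log2 change in bursa lay below that in tendon, and higher in the opposite case. Lower can mean a smaller rise, a greater fall, or a fall against a rise. Ptgs2 differed by -4.55 ± 0.88, Il1b by -2.57 ± 0.58, Mmp3 by -3.44 ± 0.94, Mmp14 by -1.37 ± 0.37, Postn by -2.74 ± 0.42, Cd8a by -1.58 ± 0.57 and the osteoclast and macrophage enzyme gene Acp5 by -2.30 ± 0.22. Globins differed too, with Hbb at -4.11 ± 0.49 and Hba-a1 at -3.87 ± 0.40, and Hba-a1 fell in bursa while it rose in tendon. Spp1 (3.27 ± 1.05), Angptl7 (3.68 ± 0.98), Cilp (3.26 ± 0.45) and Kera (2.22 ± 0.70) differed in the other direction. The change in bursa was lower for 8 of 16 proteases, 6 of 14 cytokines, 6 of 9 T and NK cell genes, 4 of 5 neutrophil genes and 4 of 6 red blood cell genes, and higher for 3 of 11 tendon cell genes (range 2 to 8). Leaving out a single library ended the call of Kera (control tendon 5, adjusted p = 0.054), of Mmp3 (control bursa 4, adjusted p = 0.053) and, for 7 of 22 libraries, of Cd8a (adjusted p up to 0.097).

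The remaining lists varied at day 3. Fibrous matrix and mast cell genes had 2 lower each. Cell division, myofibroblast, macrophage, osteoclast, endothelium, synovial lining, cartilage and B cell genes had 1 lower each, and Schwann cell and resident type macrophage genes had 1 higher each. Spp1 and Trem2 type genes had 1 higher and 2 lower of 7, hypoxia 1 higher and 4 lower of 10 and bone forming cells 1 higher and 1 lower of 6. Muscle, adipocyte, interferon, respiration and immediate early genes did not pass, and as single libraries were left out muscle had 0 to 11 higher and cartilage 0 to 5. The count was 1689 higher and 2495 lower, 40.4% higher, and without control bursae 1 and 2 this share was 56.6%. With the replicate number as a block 2458 features were called.

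The same interaction was tested at day 14 (n = 6, 5, 6 and 5). Postn differed by -4.70 ± 0.44 (adjusted p = 2.2e-10), Mmp14 by -3.05 ± 0.38, Col12a1 by -2.48 ± 0.57, Cthrc1 by -2.02 ± 0.49, Ptgs2 by -4.78 ± 0.88, Acp5 by -2.28 ± 0.22 and Top2a by -1.41 ± 0.45, each lower in bursa, while Mki67 did not pass (-0.78 ± 0.32, adjusted p = 0.058). The change in bursa was lower for 8 of 17 fibrous matrix genes (1 higher), 8 of 16 proteases, 9 of 16 cell division genes (range 7 to 13, and 12 adjusted over the list alone), 6 of 12 myofibroblast genes and 4 of 6 red blood cell genes. It was higher for Angptl7 (3.98 ± 0.97), Cilp (2.89 ± 0.45) and Pck1 (4.34 ± 1.26). Cxcl10 (4.46 ± 1.48) and Irf7 (3.43 ± 0.87) were among 8 of 13 interferon genes with a higher change, and that count ranged from 2 to 11 as single libraries were left out. Without day 14 bursa replicate 6 Cxcl10 was 0.77 (adjusted p = 0.50) and Irf7 1.34 (adjusted p = 0.048), and without control tendon 4 Cxcl10 was 4.03 (adjusted p = 0.060).

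The change in bursa was higher for muscle in 6 of 11 genes (range 1 to 11), adipocytes in 5 of 9 (2 to 6), Schwann cells in 4 of 8, tendon cells in 2 of 11 and resident type macrophages in 2 of 5. Bone forming cells had 2 higher and 3 lower of 6, hypoxia 3 higher and 2 lower of 10, synovial lining 1 higher and 1 lower of 7, cytokines 3 lower of 14 and osteoclasts 2 lower of 5. Neutrophil, macrophage, cartilage and immediate early genes had 1 lower each, and respiration (range 0 to 8) and Spp1 and Trem2 type genes 1 higher each. T and NK cell, B cell, mast cell and endothelium genes did not pass. The count was 2659 higher and 3329 lower, and 3976 with the muscle covariate.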

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

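The genes examined for single libraries far from their group were chosen after the values were seen, and the tests of group differences were planned. Dixon's ratio, at a chance of 1 in 20 per test, marked 13 of 81 values, 32 of them measures of whole libraries and 49 of them gene levels.

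Day 14 bursa replicate 6 carried a strong interferon signal: Mx1, an antiviral gene, stood at 1462 CPM against 9.38 to 46.8 in the other 5 libraries. The same library had 69.9 M counts against 12.5 to 22.6 M. Control bursa replicate 5 had Mx1 at 27.4 CPM against 2.69 to 9.41. Mki67 was 28.7 CPM in day 14 bursa replicate 4 against 13.1 to 17.2. Muscle transcripts were almost absent from day 3 bursa replicate 6, with a mean log2 CPM of -1.72 against 4.36 to 7.60.

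In tendon, day 3 replicate 1 with the bursa removed had the most muscle RNA of the 6 libraries in its group. Its Ckm was 4258 CPM against 427 to 1395, its mitochondrial share 25.4% against 11.7 to 15.5%, and its Chad 19.0 CPM against 2.18 to 5.30. Ckm was also high in day 14 replicate 4 with the bursa removed, at 2950 CPM against 649 to 1425. Postn was 27401 CPM in day 14 replicate 2 with the bursa removed against 23213 to 24744. Control tendon replicate 3 had Scx at 18.1 CPM against 29.9 to 32.5, and control tendon replicate 2 was the only control with Mmp13 counts (0.124 CPM). Day 3 replicate 6 with the bursa intact had 13.5 M counts against 17 to 18.9 M.

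Bursa and tendon differed in their response for 4184 features at day 3 and 5988 at day 14. At day 3 the difference was -4.55 for Ptgs2, -4.11 for Hbb, -3.87 for Hba-a1, -3.44 for Mmp3, -2.74 for Postn, -2.57 for Il1b, -2.30 for Acp5, -1.58 for Cd8a and -1.37 for Mmp14. It was 3.68 for Angptl7, 3.27 for Spp1, 3.26 for Cilp and 2.22 for Kera. At day 14 it was -4.78 for Ptgs2, -4.70 for Postn, -3.05 for Mmp14, -2.48 for Col12a1, -2.28 for Acp5, -2.02 for Cthrc1 and -1.41 for Top2a. It was 4.46 for Cxcl10, 4.34 for Pck1, 3.98 for Angptl7, 3.43 for Irf7 and 2.89 for Cilp, and without day 14 bursa replicate 6 it was 0.77 for Cxcl10 and 1.34 for Irf7.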

How the results depend on the processing

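All alternatives were planned except the fits without control bursae 1 and 2, without both tendons numbered 1 or 4, and with block and muscle covariate together, which were chosen after seeing the data. RLE factors and the looser and stricter filters moved no count by more than 1.5 times. With the replicate number as a block the count was 3968 for bursa at day 3, 251 for bursa at day 14, 4811 for bursa against tendon control and 2458 for the tissue difference at day 3. The block fits held only the groups compared, and injured and control bursae of equal number come from different rats. The 3968 and 251 therefore do not measure a pairing of animals, and why they lie below the main counts was not tested. Correlation by number showed in tendons at day 14, where all 6 pairs of removed and intact correlated (0.17 to 0.58), and in 5 of 6 at day 3. Between groups of different rats, equal numbers correlated in 4 of 5 pairs of day 14 removed and control tendons. The same held in 4 of 5 pairs of day 3 and control bursae, but in 1 and 0 of 5 for day 3 intact and removed tendons against control. So this correlation need not mark a shared rat. The block left 0 features of removal at both days, with 646 and 1610 unadjusted p-values under 0.05. Day 3 bursa and intact tendon correlated in all 6 pairs (0.11 to 0.27), control bursa and tendon in 2 of 5, and why the block lowered the count of the tissue difference was not tested. No paired analysis was possible for day 14 against day 3 because each animal was sampled on 1 day. A fit of only the groups compared gave 1563 for bursa at day 14, 5656 for bursa against tendon control and 2744 for the tissue difference at day 3, where the median log2 fold change of all features moved from -0.08 to 0.04 (0.07 with the replicate block). The muscle covariate, the mean of a list that holds Ckm and Acta1 and so removes their change by construction, gave 3486 and 4485 for tendon at day 3 (intact, removed), 4976 and 5855 at day 14 and 3976 for the tissue difference at day 14, the cause was not tested, and it may also take out injury effects that run with muscle loss. Counting only 2-fold changes gave 3293, 1082 and 1117 in bursa (day 3, day 14, between days), 4919, 4450, 4780 and 4583 in tendon (day 3 intact, removed, day 14 intact, removed), 1918 and 2085 between days, 3941 for bursa against tendon control, and 1716 and 2789 for the tissue differences. DESeq2 called 12, 2 and 1 features for removal at day 3, at day 14 and for their difference, where edgeR called 0. The calls at day 14 and for the difference had log2 fold changes of -25.6, 21.7 and 23.3, too large to be read as measured effects. In the self-test DESeq2 called 40, 34 and 42 unchanged features in these comparisons, against 5, 9 and 12 with edgeR. The simulated counts held planted changes and used edgeR dispersions, and DESeq2 ran there with other settings and filtering than in the real fit. They therefore do not give the number of false calls among the real ones. With an estimated correlation the gene lists lost all camera calls (0). Without control bursae 1 and 2 the share of higher changes in bursa against tendon at day 3 moved from 40.4% to 56.6%. For 515 pairs of a gene and a comparison, 10468 alternative values left the call as it was in 10163, lost it in 245, gained it in 51 and turned direction in 9. Direction was compared only for genes called in the main fit. A gene called in neither fit counts as unchanged whatever its direction. Direction turned with the muscle covariate for Ckm in day 3 tendon (0.45 intact, 0.26 removed) and in bursa against tendon control (1.398), for Acta1 (0.32) in day 3 tendon, Mkx (0.11) in day 14 tendon and Scrg1 (2.47) in the tissue difference at day 14, and for Ndufs1 (0.32) in bursa at day 3 without control bursae 1 and 2. Leaving out single libraries, Chad in bursa at day 14 ranged from -5.78 to 0.61 and Scrg1 from -7.16 to 5.29, both turning without control bursa 4. Leave-one-out counts ranged from 1872 to 3518 for bursa at day 14, 6648 to 7734 at day 3, and stayed at 0 for removal. Depths of 12.4 to 69.9 M counts limit the genes of lowest count.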

Other observations

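The tests of brown fat, of muscle RNA in the bursa, of mitochondrial transcripts alone, of the respiration fall, of the muscle share and of unequal muscle RNA were chosen after the result was seen. Most exchanges of sample labels were written before, and those for bursa at day 3, for removal at day 14, for the tissue difference at day 14 and within pairs at day 3 after.

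Embryonic muscle genes rose in part of the day 3 bursae. Actc1 had 531 and 186 CPM in replicates 1 and 5, and 12.1 CPM or less in the other 4. Replicates 1 and 5 also had the highest mean muscle level of the day 3 bursae (6.28 and 7.60 log2 CPM, 5.28 or less in the others). Whether Actc1 follows muscle content was not tested. Of 9 genes of embryonic and regenerating muscle, a list written after this was seen, 7 rose in bursa at day 3, 5 rose and 3 fell in tendon at day 3 with the bursa intact, 5 rose and 1 fell with it removed, and 0 passed for removed against intact (median 0.93).

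Ucp1, the heat-making gene of brown fat, stood at 3804, 1418, 5.67, 0 and 0 CPM in control bursae 1 to 5. Over the 17 bursa libraries, with group means removed, the mitochondrial share correlated at 0.86 with the mean level of 11 brown adipocyte markers, and brown fat dissected with the bursa may account for the share. Some of these markers are active in muscle too, and the muscle list correlated with the share at 0.44, so muscle RNA stays open as a part. Mitochondrial transcripts alone, from RNA quality or handling, would leave nuclear respiration genes level, but these 13 genes correlated with the share at 0.95. Control bursae 1 and 2 had shares of 48.9 and 53.5%, against 11.3 to 29.1% in the other bursa libraries, and weigh heavily in all of these correlations. No correlation was run without them. The values therefore largely repeat the contrast of these 2 libraries and do not decide between the explanations. The markers were listed after the mitochondrial shares and some fat genes had been seen.

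The fall of the respiration list in the day 3 bursa rested on control bursa replicates 1 and 2. Of 13 genes 12 fell with all libraries, and 0 fell without these 2. They were picked by a mitochondrial share that runs with this list, so leaving them out does not decide whether brown fat is the source. Without them Ndufs1 turned from a fall to 0.32 (adjusted p = 0.41).

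Muscle transcripts fell in every injured tendon group, which could by arithmetic raise the share of all other genes. TMM scaling works against such a shift, and the median log2 fold change of all features was -0.045 at day 3 with the bursa intact. A lower share of muscle RNA as the whole cause would move the other lists alike. In day 3 tendons with the bursa intact, the only group tested, their medians lay 5.24 log2 apart. They ran from cartilage at -2.90 and tendon cell at -2.49 to fibrous matrix at 1.66 and macrophage at 2.34. These lists were already known to move in opposite directions when the test was chosen, so it adds nothing to the list results. In removed against intact tendons at day 3, unequal muscle RNA could account for the excess of small p-values, since their number was 714 with the muscle covariate, against 1289 without it and 821.75 expected, and 896 with this covariate and the replicate block against 1610 with the block alone.

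Sample labels were exchanged within each comparison up to 100 times, the real grouping included. Only 1 grouping, the real one, reached its count for bursa at day 3 (highest other count 6506), bursa at day 14 (875), bursa day 14 against day 3 (1173), tendon at day 3 with the bursa intact (7156) or removed (8841), tendon at day 14 intact (6228) or removed (7229), day 14 against day 3 intact (3673) or removed (3171), and bursa against tendon control (6439). Chance is unlikely in these comparisons but not excluded, since at most 100 groupings were used and the exchanges take libraries as independent. Exchanges that keep part of the real difference give high counts too. For the differences between tissues the exchanges decide nothing about chance, because an exchange that reverses a tissue turns the difference of the injury effects into their sum: 6 groupings reached 4184 at day 3 (highest other 8738) and 3 reached 5988 at day 14 (6814).

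For bursa removal, edgeR called 0 features at day 3, at day 14 and for their difference, a count that any grouping reaches (100 of 100, highest other 6, 2 and 1), so the numbers of unadjusted p-values were compared, and there chance cannot be excluded. For unadjusted p-values under 0.05, 24 groupings reached 1289 at day 3 (highest 2845), 86 reached 214 at day 14 (highest 1635) and 94 reached 254 for the difference (highest 2642). These higher counts in other groupings point to a structure of the samples that does not follow the treatment. Which structure it is was not tested on these groupings, though free exchanges break the numbered pairs, which correlated in all 6 at day 14 and in 5 of 6 at day 3. With the replicate number as a block at day 14, 13 of 32 exchanges within pairs reached 646, with a highest other count of 2201. At day 3 2 of 32 reached 1610, the other with 2069. That other exchange swapped only the tendons numbered 3, a pair that did not correlate (-0.04), and kept the real labels of all other pairs. It thus kept most of the real grouping. Chance cannot be excluded at either day.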
